A study of Arabidopsis thaliana with 44 samples.

How the data were processed

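The 44 deposited tables give the reads of 1 sequencing run each, from rosette leaves of 21-day-old plants, as whole counts per 1 kb bin of the TAIR10 genome; that they are counts was read from the values, which are whole numbers that sum to a different total in each run. The authors name CASAVA 1.8.2, Bowtie 0.12.8 and TAIR10 without stating their roles, and the counting of reads that span bins, duplicates and reads that map to several places is not given in the sources used here. Repeats around the centromeres can hold reads of many copies, so their values depend on that counting. The labels list antibodies for lysine 4 methylation but none for H3T3ph or H3 in the extraction protocol. Input DNA was not analysed here, and H3 served as the background measured in the same way.

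Runs of 1 group were compared in pairs. Pairs with an excess coefficient of variation under 3.16% between 10 kb bins, beyond sampling noise, were added together as 1 library (13 pairs; chi-square per degree of freedom between 1 kb bins 1.02 to 1.48, against 1.64 to 62.3 in other pairs), which left 31 libraries. This limit was set after the pairs were compared. Run totals were 2772716 to 24620238 reads. Reads of the organelles were left out of all tests. A library was said to have coverage gaps when over 0.1% of bins with at least 10 reads expected held 0. The expected reads came from the profile pooled over all libraries of all antibodies. This rule was chosen after the data were seen. Intervals and floors cover counting error only.

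Reads were added up in 10 kb bins (11905 of 11916 tested) and over genes, as all 1 kb bins that overlap a gene in the RefSeq annotation of TAIR10.1 (37899 genes). Positions given are those of these bins. H3K4me1 reads were compared with the inner bins of protein-coding genes in 15 chromosome parts, at shifts of up to 10 kb, and matched best without any shift in 15 of 15. For each antibody a quasi-likelihood model was fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, 1 mean per group, all groups sharing the spread) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold; standard errors are the log2 fold change divided by the square root of F. DESeq2 1.42.0 was the other tool. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over 24 tests of 6 lists: osmotic and ABA response (42 genes), photosynthesis (24), developmental and seed genes silent in leaves (19), housekeeping (9), MUT9-like kinases (4) and genes in pericentromere windows. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for the rest.

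The pericentromere windows were 12 to 18 Mb on chromosome 1, 1 to 7 on chromosome 2, 10 to 17 on chromosome 3, 2 to 6 on chromosome 4 and 9 to 16 on chromosome 5, or 25.2% of nuclear bins. The ratio of reads per kb inside to those in the arms was taken per library and compared by two-sided exact permutation tests. The windows, lists, tests, threshold and the rule for named genes were chosen before the data were examined. That rule takes the genes past the threshold whose groups do not overlap, 10 in each direction for H3T3ph and 5 for other antibodies by size of change, or, where none passes, the 5 with the smallest p in each direction; up to 8 members of each list with the largest H3T3ph change; the 4 kinases; and the 5 bins with the largest change in each direction. The stretch of chromosome 5 was found after the data were seen, as a run of at least 100 kb in which the running median log2 of mutant over Col0, averaged over the 4 antibodies, passed 0.5.

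Alternatives were library size or arm-based scaling, no filter, DESeq2, fits of the compared groups alone, a block for replicate number, 100 kb bins, genes with 1 kb on each side, narrow windows, medians, the 1% of bins with most reads left out, each library left out in turn, bin changes relative to those of H3, and an estimated correlation. Added after the data were seen were each run as a replicate, coverage gaps as a covariate, ratios relative to H3, a crossed block, the block and left-out libraries for gene lists, and leaving out the stretch. The tests were tested on simulated data with 200 changed features at the estimated spread. The simulated libraries were independent, without the pairs and library sets of the real ones, so the shares recovered may not hold for the real data. Double-mutant H3 has 1 library per treatment and served as background for the bins of other antibodies and for the density of the stretch. H3 libraries of equal replicate number in Col0 deviated together (correlations 0.946, 0.715 and 0.897), so the numbers were taken to pair them. This comes from the data, not the labels. Where both sides had 2 libraries, equal numbers correlated at 0.881 (Col0 H3K4me1), 0.767 (mutant H3K4me1), 0.743 (mutant H3T3ph) and −0.2 (Col0 H3K4me3). Crossed numbers there give the opposite sign by construction. A few values that coincide with a number typed in the scripts or in a gene name are not printed, such as the SD of HSFA6A in Col0; they stand in the tables.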

Results

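Rosette leaves of Arabidopsis thaliana, 21 days old, were profiled by chromatin immunoprecipitation and sequencing with 4 antibodies. They recognise histone H3 itself, H3 phosphorylated at threonine 3 (H3T3ph), and H3 carrying 1 or 3 methyl groups on lysine 4 (H3K4me1 and H3K4me3). Plants were watered or placed for 5 hours in 30% polyethylene glycol (PEG), an osmoticum that withholds water from the plant. The plants were wild type (Columbia-0, Col0) or a double mutant with lowered AT3G03940 and a second locus that the labels write without its letter G, read here as AT5G18190. Both loci encode MUT9-like kinases (MLK2 and MLK1), relatives of the casein kinase 1 family. The series title names the regions around the centromeres as the place where H3T3ph changes.

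The 44 sequencing runs fell into 16 groups of antibody, genotype and treatment. Within 13 pairs of runs the counts differed by little more than sampling noise (excess coefficient of variation at most 2.88%, against 5.71% to 38.5% for other runs of 1 group), and each such pair was counted as 1 library. A library is named here by both numbers, as in replicate 1/2. This left 31 libraries. Col0 had 3 watered and 3 PEG libraries for H3, 2 and 3 for H3T3ph, 2 and 2 for H3K4me1, and 2 and 2 for H3K4me3. The double mutant had 2 and 2 for H3T3ph and for H3K4me1, but 1 and 1 for H3 and H3K4me3. Its H3K4me3 values carry no replicate error and the lone library was assumed to vary like those of the other groups. Libraries held 9668715 to 21014489 reads for H3, 2772716 to 22769851 for H3T3ph, 6816638 to 27592091 for H3K4me1 and 17777170 to 46442123 for H3K4me3. The labels do not say that the samples came from separate plants, so p-values measure only the spread between these samples. In 10 Col0 libraries 0.130% to 3.69% of the 1 kb bins with at least 10 reads expected held none, against at most 0.0691% in the other 21. This set of libraries with coverage gaps was treated as a technical batch found after the data were seen. Expected reads were pooled over all antibodies, so for lysine 4 methylation gaps cannot be told apart from strength of enrichment. Col0 H3K4me1 libraries with gaps had log2 pericentromere to arm ratios of −0.57 and −0.28, the others 1.12 and 0.69. For Col0 H3K4me3 they were −0.11, 0.49 and −0.51 with gaps and −0.08 without.

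In watered Col0 leaves, H3T3ph and H3 were denser in the pericentromeres than in the arms. H3K4me1 and H3K4me3 had lower mean pericentromere to arm ratios than H3. The exact permutation test of 2 against 3 libraries cannot call such a difference. Reads per kb in the pericentromere windows of the 5 chromosomes were 2.32 times those in the arms for H3T3ph (log2 ratio 1.21 ± 0.06, SD, n = 2) and 2.69 times for H3 (1.43 ± 0.25, SD, n = 3). For H3K4me1 the 2 libraries stood apart, at −0.57 and 1.12 (mean log2 ratio 0.27), and the log2 ratio was −0.09 ± 0.02 for H3K4me3 (SD, n = 2). Medians of bins, which are not moved by a few repeats, gave 0.38 ± 0.01 for H3T3ph, 0.40 ± 0.19 for H3, −0.75 ± 0.83 for H3K4me1 and −0.69 ± 0.02 for H3K4me3. On every chromosome the median pericentromeric H3T3ph lay above the arms, from a log2 of 0.27 ± 0.07 on chromosome 1 to 0.69 ± 0.11 on chromosome 4 (SD, n = 2). Single repeats held much of the signal. The first 10 kb of chromosome 2 lie outside the windows and count as arm. They took on average 7.25% of nuclear reads over the 31 libraries of all antibodies. The adjacent bins of chromosome 3 from 14190001 to 14210000, inside the windows, took 6.18% and 4.67%. Against H3 the difference in log2 ratio was −0.21 for H3T3ph (two-sided exact permutation p = 0.6), −1.15 for H3K4me1 (p = 0.2) and −1.52 for H3K4me3 (p = 0.2), where 0.2 is the smallest p that 2 against 3 libraries allow. Within libraries with gaps and within the others these differences were −0.24 and −0.22, −2.07 and −0.27, and −1.60 and −1.47. Leaving out watered H3K4me1 replicate 1/2 brought the H3K4me1 difference to −0.31, and leaving out replicate 3 brought it to −2.00. Over all 10 comparisons of this ratio made here, the Benjamini-Hochberg adjusted p was 0.667 to 1.

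**Figure D1:**
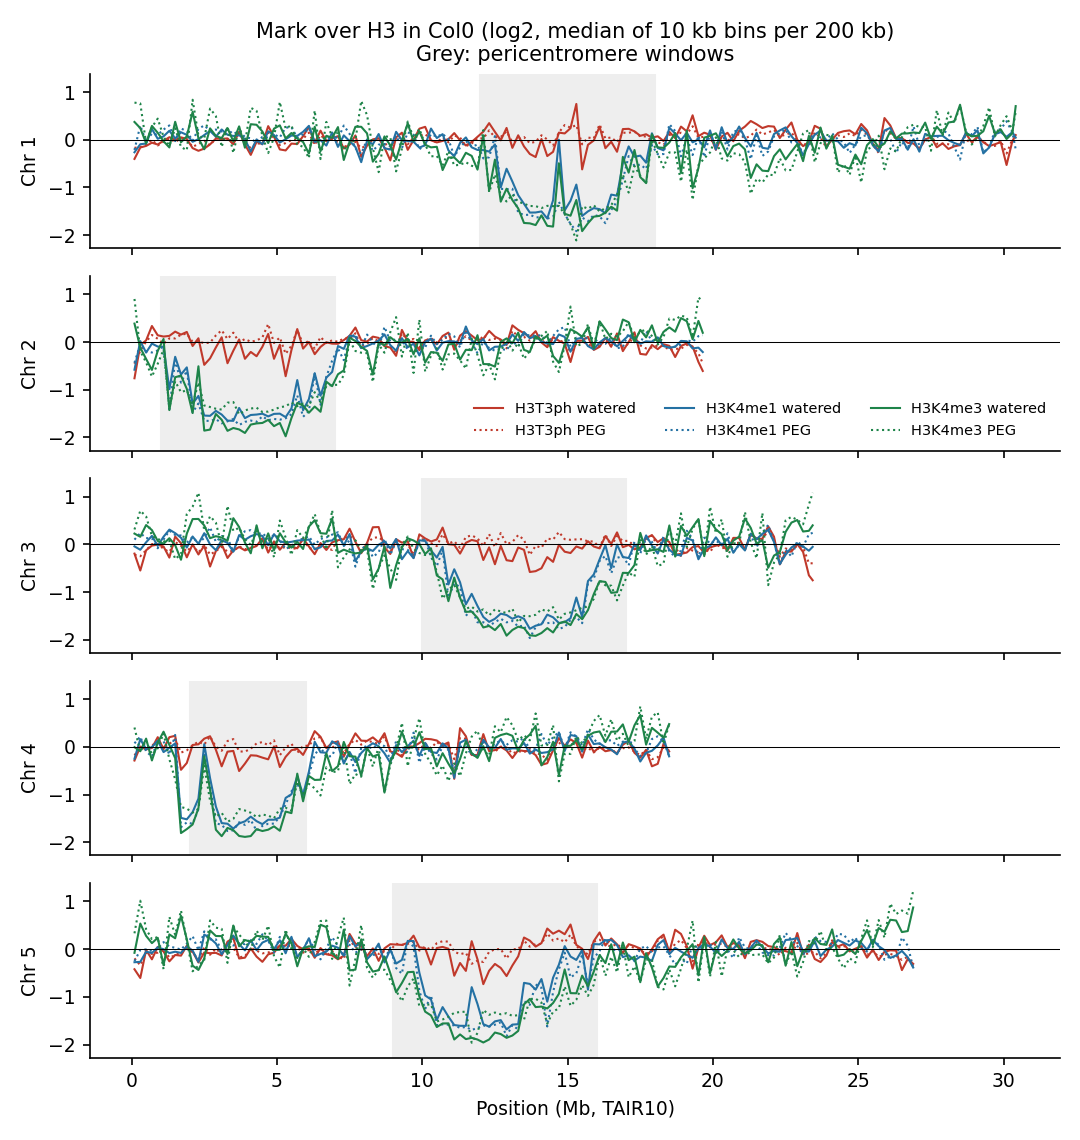
Log2 ratio of each modification to H3 along the 5 chromosomes of Col0 (position in Mb on the horizontal axis; each line is a median of 10 kb bins in steps along the chromosome), watered as solid and PEG as dotted lines, with the pericentromere windows in grey. H3K4me1 and H3K4me3 drop inside the windows while H3T3ph runs near 0 in both treatments, where its genes had a watered median of −0.02.

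Under PEG, pericentromeric H3T3ph in Col0 had a higher mean than in watered leaves. The exact permutation test of 3 against 2 libraries cannot give a p below 0.2, so this stays uncalled. The log2 pericentromere to arm ratio was 1.35 ± 0.13 (SD, n = 3) in PEG and 1.21 ± 0.06 (SD, n = 2) in watered libraries, a difference of 0.13 (two-sided exact permutation p = 0.4, smallest possible 0.2). By medians of bins the difference was 0.06 (exact permutation p = 0.6), and without PEG replicate 4/5 the difference of means was 0.21. The mean ratio was higher in PEG on chromosomes 1, 3, 4 and 5 and lower on chromosome 2. The mean lay furthest above watered on chromosome 3 (2.53 ± 0.55 against 2.01 ± 0.39), with 0.71 ± 0.09 against 0.63 ± 0.03 on chromosome 1 and −0.23 ± 0.41 against 0.15 ± 0.29 on chromosome 2 (SD, n = 3 and 2). By medians of bins all 5 chromosomes had higher values in PEG, chromosome 2 at 0.55 ± 0.16 against 0.47 ± 0.01. The mean of the chromosome 2 arms includes its read-rich first 10 kb. Within the libraries with gaps (2 PEG, 1 watered) the difference was 0.17, and within the others (1 and 1) it was 0.02. H3 itself differed by −0.04 between treatments (exact permutation p = 0.9, smallest possible 0.1), with 0.17 and −0.15 in the 2 sets. Leaving out PEG replicate 1/2 or watered replicate 4 turned its sign (0.20 and 0.06). For H3K4me1 the difference was −0.06 (0.30 and −0.43 in the 2 sets) and for H3K4me3 0.08 (0.10 within the set with gaps, and no PEG library in the other), each with an exact permutation p of 1 and a smallest possible 0.333. Single libraries decided both: H3K4me1 stood at −0.91 and 0.78 without watered replicate 1/2 or 3 and at 0.42 and −0.55 without PEG replicate 1/2 or 3/4, and H3K4me3 at −0.42 and 0.58 without PEG replicate 1/2 or 3.

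**Figure D2:**
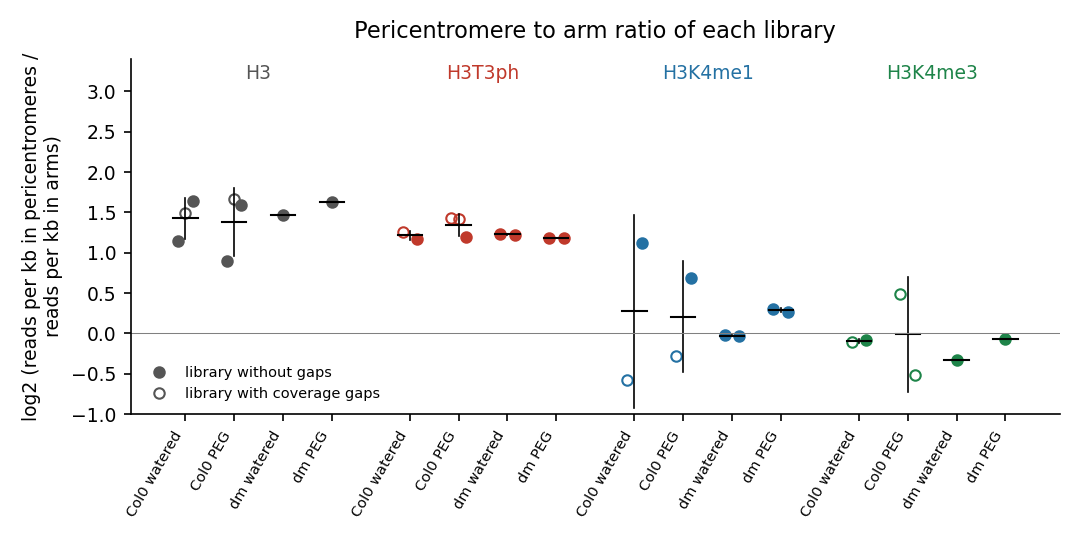
Log2 of reads per kb in the pericentromere windows over reads per kb in the arms, 1 point per library, grouped by antibody, genotype and treatment; horizontal bars are group means, vertical lines ± SD, and open points are libraries with coverage gaps. The 3 Col0 PEG libraries of H3T3ph spread from 1.19 to 1.43 and overlap the watered libraries, the lower of which stands at 1.17.

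At single genes and 10 kb bins, H3T3ph showed no change under PEG in Col0 that passed the main test. The lowest p-values belonged to genes with less H3T3ph in PEG: XTH24, a xyloglucan endotransglucosylase of the cell wall (chromosome 4, bins 14819001 to 14821000), had a log2 fold change of −1.03 ± 0.24 (standard error; 5.51 ± 1.89 CPM, counts scaled to library size, SD, n = 3, against 12.1 ± 0.435, n = 2), AT3G15810 −0.95 ± 0.22, the microRNA gene MIR5651 −1.01 ± 0.26, BT4 −0.64 ± 0.15 and AT3G26085 −0.55 ± 0.14. In the other direction stood AT1G63470 (0.50 ± 0.14), AT3G13140 (0.49 ± 0.14), AT3G18570 (0.74 ± 0.22), AT3G59980 (0.65 ± 0.19) and the noncoding AT3G09905 (0.94 ± 0.29). None passed (adjusted p 1.00 for all 10). Of 11905 bins edgeR called 0, with 76 at an unadjusted p under 0.05, and DESeq2 called 0; of 37899 genes edgeR called 0, with 353 under 0.05, and DESeq2 called 0. The median bin changed by 0.04 in pericentromeres and −0.02 in arms, and scaling by library size in place of TMM shifted all changes by −0.19. With a block for replicate number some bins and genes passed, as given with the alternatives. The numbers do not pair the Col0 H3T3ph libraries cleanly. Watered 3/4 shares a number with both PEG 3 (correlation −0.557) and PEG 4/5 (0.795). The block joined it to PEG 3 and left PEG 4/5 alone, so PEG 4/5 added nothing to the blocked estimate. XTH24 and AT3G18570 each passed in 1 alternative. In simulated data with this spread, but without pairs or library sets, the bin test recovered 25.4%, 79.1% and 98.5% of 1.5-, 2- and 4-fold changes. The gene test recovered 2.99%, 23.9% and 77.3%.

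No gene list fixed before the data were examined passed the test planned for lists for H3T3ph under PEG. Of the 42 members of the osmotic and abscisic acid (ABA) response list, 30 had a positive log2 fold change (median 0.12) and 0 passed, over all genes or adjusted over the list alone. The largest were DREB1A (0.60 ± 0.40), a cold and drought response transcription factor, the protective protein genes COR15B (0.52 ± 0.30), LTI78, also named RD29A (0.46 ± 0.30), LEA4-5 (0.46 ± 0.25) and RAB18 (0.43 ± 0.38). Next came NCED3 (0.37 ± 0.30), which encodes the step that limits ABA synthesis. HB-12 (−0.42 ± 0.31) and the ABA-degrading enzyme gene CYP707A1 (−0.37 ± 0.18) had negative values. Of 24 photosynthesis genes 16 had positive values (median 0.07, 0 passing), with CAB3 at 0.47 ± 0.31, LHCB4.1 at 0.36 ± 0.32, LHCB3 at 0.36 ± 0.21, PSBO1 at 0.35 ± 0.30, CAB2 at 0.35 ± 0.31 and LHCA2 at 0.34 ± 0.23, while RBCS1A stood at −0.62 ± 0.51 and RBCS1B at −0.32 ± 0.26. Among 19 developmental and seed genes chosen as silent in leaves (median −0.10, 0 passing), the 8 members with the largest values were CRA1 (0.54 ± 0.37), PI (−0.54 ± 0.65), CRU3 (0.45 ± 0.36), SEP3 (−0.42 ± 0.58), AG (−0.25 ± 0.42), MEA (−0.22 ± 0.36), SEP2 (−0.21 ± 0.31) and LEC2 (−0.18 ± 0.15), each at an adjusted p of 0.964 within the list. The 9 housekeeping genes had a median of −0.09, with 0 passing, from −0.30 ± 0.26 for AT5G60390 to 0.26 ± 0.30 for UBQ5; AT4G34270 stood at −0.26, AT2G28390 at 0.22, GAPC1 at −0.20, ACT2 at −0.15, PP2AA3 at −0.09 and UBQ10 at −0.08. Camera, a test of a list against all other genes, called none of the 6 lists for H3T3ph: adjusted p was 0.201 for osmotic and ABA response, 0.0599 for photosynthesis, 0.622 for silent genes, 0.670 for housekeeping, 0.927 for the 4 MUT9-like kinases and 0.101 for the 7798 genes in pericentromere windows. With an estimated correlation the adjusted p was 0.881 or above for every list. With a block for replicate number, camera called osmotic and ABA response (adjusted p 1.72e-04), photosynthesis (0.00166) and pericentromere genes (0.0274) higher in PEG. That block was not fitted with an estimated correlation, and the numbers do not pair these libraries cleanly. It joined watered 3/4 to PEG 3, so PEG 4/5 added nothing to these calls. Leaving out H3T3ph PEG 4/5 without a block likewise raised the number of lists called over all antibodies, as given with the alternatives.

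No single gene or bin passed the main test, which takes no account of pairs, for H3 or H3K4me1 under PEG. A call of lower H3 over pericentromere genes was lost with an estimated correlation. Of the 7791 pericentromere genes tested for H3, 4955 had negative changes (median −0.07, 0 passing over all genes or adjusted over the list alone) and camera called the list lower at an adjusted p of 0.00821; with an estimated correlation the adjusted p was 0.881. The genes with the smallest H3 p-values were LCR47 (1.44 ± 0.48), AT3G03715 (1.26 ± 0.46), AT1G12411 (1.48 ± 0.56) and MIR2934 and MIR782, which share bins (1.47 ± 0.57). On the other side stood AT3G47920 (−0.61 ± 0.22), AT1G47595 (−0.54 ± 0.25), AT1G39750 (−0.64 ± 0.31), AT3G06065 (−0.55 ± 0.28) and RALFL34 (−0.52 ± 0.26). For H3K4me1 they were ARL (0.78 ± 0.20), AT1G15125 (0.83 ± 0.22), MIR408 (0.83 ± 0.22), a copper-responsive microRNA gene, AT2G08535 (0.95 ± 0.27) and EBF2 (0.75 ± 0.23), which acts in ethylene signalling. Lower values had AT2G30760 (−0.92 ± 0.24), MIR166f (−0.92 ± 0.25), the defence regulator WRKY33 (−0.61 ± 0.17), AT2G39560 (−0.84 ± 0.23) and AT1G13608 (−1.02 ± 0.28). By edgeR 0 bins were called for H3 (3 at an unadjusted p under 0.05, DESeq2 0) and 0 for H3K4me1 (60, DESeq2 0), and 0 genes (30 and 328, DESeq2 0 for both). Each of these counts is a share well below 0.05 of the features tested. The main test was thus strict here, and its lack of calls does not show that nothing changed. With the replicate number as a paired block 10 H3 bins passed, 9 higher and 1 lower in PEG, and 0 genes. Camera with this block called 2 further lists lower for H3, osmotic and ABA response (adjusted p 0.0274, without the block 0.0599) and photosynthesis (0.0381, without it 0.134). Without the block the adjusted p was 0.881 for each with an estimated correlation, and the block was not fitted with one. The bin test recovered 5.97%, 47.8% and 90.9% of simulated 1.5-, 2- and 4-fold changes for H3 and 0%, 1.49% and 60.6% for H3K4me1.

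In the main fit H3K4me3 was called higher under PEG in Col0 at 147 genes and lower at 1. The count depended on scaling and on single libraries, and its direction on scaling, as the next paragraph gives. The pair MRD1 (AT1G53480) and the overlapping noncoding AT1G07887 (chromosome 1, 19963001 to 19965000) rose most, by a log2 fold change of 2.04 ± 0.33, from 16.5 ± 0.440 CPM (SD, n = 2) to 67.8 ± 10.3 (n = 2; adjusted p = 1.5e-05). HEI10, a meiotic crossover gene, spans the same 2 bins and 2 more, so its value (1.79 ± 0.36) counts their reads again. AT1G67623 (1.99 ± 0.34) and BBX31, a B-box factor (1.79 ± 0.35), rose as well, and AT3G51400 fell (−1.65 ± 0.33). Of the 42 osmotic and ABA response genes, 1 passed over all genes (LEA4-5, 1.33 ± 0.31, adjusted p = 0.0147) and 3 adjusted over the list alone, the others being CBF3, the DREB1A named above (1.21 ± 0.39), and ZAT12 (1.00 ± 0.31), a zinc finger stress regulator; the list median was 0.14, with 22 values positive and 20 negative. Of the 24 photosynthesis genes 19 had positive values (median 0.73), 0 passed over all genes and 3 adjusted over the list alone: LHCB1.2, also named CAB3 (1.81 ± 0.52), LHCB1.1, also named CAB2 (1.65 ± 0.57) and LHCA2 (1.51 ± 0.48). Camera called both lists higher (adjusted p 0.0464 and 8.9e-07), and the adjusted p was 0.881 for each with an estimated correlation. Among 10000 random lists of the same watered H3K4me3 level, their medians stood at percentiles 89.5 and 82.0. The other 4 lists had adjusted camera p of 0.437 to 0.927, and 26 of the 7798 pericentromere genes passed. The change followed the starting level: by 20 classes of watered H3K4me3, the median went from −0.35 in the lowest to 0.73 in the highest.

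In all, edgeR called 148 of 37899 genes for H3K4me3 under PEG (3686 at an unadjusted p under 0.05, DESeq2 1592). Of 11905 bins 16 passed, 15 higher and 1 lower, 4 of them in pericentromere windows. The largest were chromosome 5, 9000001 to 9010000, which holds GATA12 (1.37 ± 0.30), 24500001 to 24510000 with the receptor-like kinase gene RLK1 and the MADS-box gene AGL8 (1.32 ± 0.29) and 8980001 to 8990000 with the AP2-domain factor tny (1.31 ± 0.27), chromosome 2, 12180001 to 12190000 with the LOB-domain gene LBD11, and chromosome 1, 23890001 to 23900000 with AT1G64370 and AT1G64380 (1.28 ± 0.30). The lower bin was chromosome 5, 14080001 to 14090000, around AT5G35935 (−1.33 ± 0.27). The calls depended on scaling and on each library: library size scaling shifted all changes by −0.43 and left 1 bin and 10 genes, 8 of them lower. Without watered replicate 1/2 or 3, PEG replicate 1/2 or PEG replicate 3, the counts were 0, 0, 624 and 265 bins and 1, 2, 1162 and 8 genes, and with coverage gaps as a covariate 0 bins and 2 genes.

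In the double mutant, no bin passed the main test for H3T3ph between PEG and watered leaves. With a block for replicate number bins did pass, as given with the alternatives. Libraries of equal number deviated together there (correlation 0.743). The pericentromere to arm ratio was lower in both PEG libraries than in both watered ones. The log2 ratio was 1.18 ± 0.01 in PEG and 1.23 ± 0.01 in watered libraries (SD, n = 2 each), a difference of −0.05 (exact permutation p = 0.333, the smallest 2 against 2 libraries allow). The Col0 difference was 0.13 over all libraries and 0.02 within those without gaps (1 against 1). No mutant library had gaps, and the differences of the 2 genotypes were not tested against each other. The median bin moved by −0.03 in pericentromeres and 0.00 in arms. By edgeR 0 of 11905 bins passed, with 27 at an unadjusted p under 0.05 and 0 by DESeq2. Whether genotypes differed in their response was tested as an interaction: 0 bins passed for H3T3ph (65 under 0.05, DESeq2 0), 0 for H3K4me1 (11, DESeq2 0) and 0 for H3K4me3 (376, DESeq2 0), the last giving 26 without Col0 PEG replicate 1/2. Library size scaling shifted the H3T3ph interaction by 0.19 and that of H3K4me3 by 0.48.

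A stretch of chromosome 5 from 16157001 to 22320000 (6.163 Mb) carried about double the reads in the mutant with every antibody, H3 included. Relative to the chromosome arms and to Col0, its log2 density was 1.02 ± 0.05 over all 12 mutant libraries (SD; lowest 0.91) and lay between −0.12 and 0.10 in the 19 Col0 libraries. By antibody it was 0.99 ± 0.01 for H3 (n = 2), 0.99 ± 0.06 for H3T3ph (n = 4), 1.03 ± 0.02 for H3K4me1 (n = 4) and 1.09 ± 0.01 for H3K4me3 (n = 2). The stretch holds 1948 annotated genes, 1608 of them protein coding, among them LTI78 (RD29A), LHCB3 and CRA1. AT5G18190, at 6009001 to 6015000 on the same chromosome, lies outside it. A search of the mean over the 4 antibodies for stretches of at least 100 kb with a log2 shift over 0.5 found 1 higher and 0 lower. It does not speak of shifts in 1 antibody alone.

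**Figure D3:**
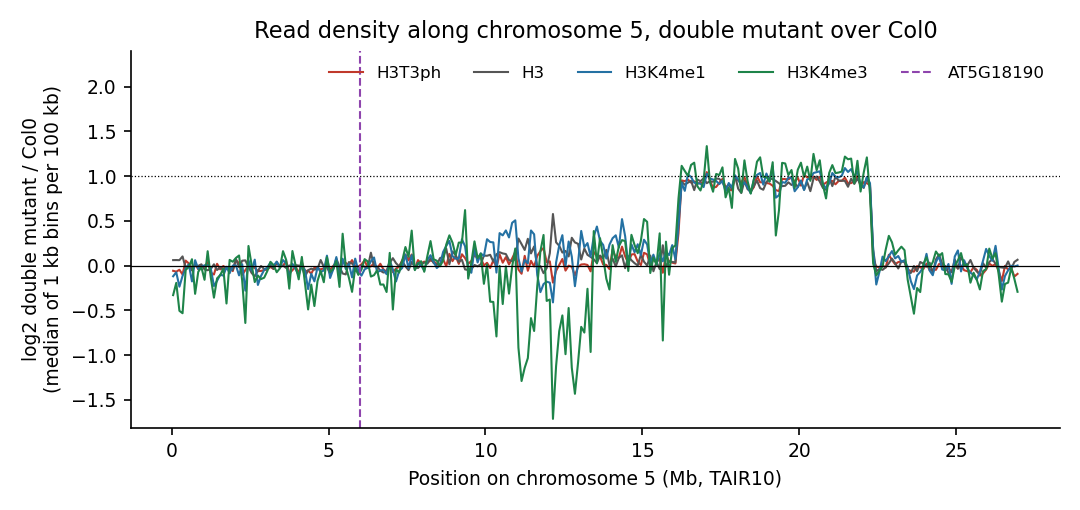
Log2 of the double mutant over Col0 for each antibody along chromosome 5 (position in Mb; median of 1 kb bins in 100 kb steps), with the dotted line at a doubling and the dashed line at AT5G18190. All 4 antibodies step up to about 1 between 16157001 and 22320000. H3K4me3, with 1 mutant library per treatment, varies most on the rest of the chromosome and dips below the others in the pericentromere.

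H3T3ph reads in the mutant lay above Col0 in that stretch, as did those of H3 (log2 density 0.99 for both). In watered plants 5 bins outside it were called lower, and none of them was called once the stretch was left out. In watered leaves 446 of 11905 bins passed, 441 higher and 5 lower, and all 441 lay in the stretch, whose 618 bins had a median log2 fold change of 0.94. The highest were chromosome 5, 19020001 to 19030000 (1.24 ± 0.22), 19190001 to 19200000 with the immune receptor gene ADR1-L3 (1.21 ± 0.24), 19060001 to 19070000 (1.19 ± 0.17), 19960001 to 19970000 with HRB1 and APRR4 (1.19 ± 0.09) and 17060001 to 17070000 (1.18 ± 0.12). The 5 lower bins were chromosome 3, 17900001 to 17910000 with CEP3 and BT2 (−0.71 ± 0.14), 7100001 to 7110000 (−0.61 ± 0.14) and 17170001 to 17180000 with MIR5651 and RDUF1 (−0.57 ± 0.13). The others were chromosome 2, 17270001 to 17280000 with ERD15 (−0.50 ± 0.10), and chromosome 5, 24290001 to 24300000 with AT5G60390 and the SUMO ligase gene SIZ1 (−0.42 ± 0.09). Of the genes, 337 rose, all in the stretch, and 1 fell. Among them were AT5G47300 (1.51 ± 0.22; 27.9 ± 3.23 against 9.82 ± 1.84 CPM, SD, n = 2 each, adjusted p = 0.0439), SPCH, the regulator that starts the stomatal lineage (1.51 ± 0.16), AT5G48420 (1.40 ± 0.24), AT5G47920 (1.35 ± 0.16), AT5G50510 (1.32 ± 0.21), AT5G54970 (1.31 ± 0.21), AT5G06655, AT5G42965 (1.29 ± 0.23), the MADS-box gene AGL83 (1.29 ± 0.20) and AT5G52780 (1.28 ± 0.22). AT2G33830 fell by 1.49 ± 0.27. The value of AT5G42965 turned negative when 1 kb on each side of the gene was added. With the stretch left out 0 bins passed, and relative to the change of H3 itself 0 passed. Without mutant replicate 1 or 2 there were 273 and 220 bins and 0 genes, without Col0 replicate 1/2 94 genes (84 lower) and without 3/4 0 genes, and scaling by library size or on the arms left 0 genes. The bin test recovered 11.9%, 62.7% and 95.5% of simulated 1.5-, 2- and 4-fold changes.

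Under PEG the H3T3ph difference between genotypes lay in the same stretch, at 472 bins and 616 genes, all higher in the mutant. The 2 treatments shared 428 higher bins. The highest bins were chromosome 5, 20210001 to 20220000 (1.34 ± 0.26), 20650001 to 20660000 with the sugar transporter gene SWEET10 (1.34 ± 0.26), 20380001 to 20390000 (1.26 ± 0.22), 17050001 to 17060000 with MRN1, of triterpene synthesis (1.26 ± 0.12), and 18260001 to 18270000 with RTL3 and RL2 (1.24 ± 0.16). The genes led with AT5G54145 (1.63 ± 0.29), the heat shock factor HSFA6A (1.58 ± 0.25; 12.9 ± 0.974 CPM, SD, n = 2, against 3.97, n = 3), WRKY24 (1.47 ± 0.28), AT5G53490 (1.46 ± 0.25), AT5G43680 (1.45 ± 0.28), AT5G44910 (1.45 ± 0.20), AT5G45440 (1.41 ± 0.20), AT5G50780 (1.40 ± 0.23), AT5G54480 (1.38 ± 0.18) and AT5G41030 (1.37 ± 0.20). With the stretch left out, or relative to H3, 0 bins passed; library size scaling shifted all changes by 0.23. Without mutant replicate 2 there were 205 bins; without Col0 PEG replicate 4/5 there were 1023 genes, and without Col0 PEG replicate 1/2 or 3 or mutant replicate 1 or 2 there were 0 genes. The pericentromere to arm ratio differed between genotypes by 0.01 in watered leaves (exact permutation p = 1, smallest 0.333) and by −0.16 under PEG (p = 0.2, the smallest possible). Within the libraries without gaps the differences were 0.05 and −0.01, no mutant library having gaps; without Col0 watered replicate 3/4 the first was −0.03. The doubled stretch lies in the arms and lowers the mutant ratio: without it the differences were 0.09 and −0.08, and 0.13 and 0.06 within the libraries without gaps.

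H3K4me1 reads were also higher in the mutant on the chromosome 5 stretch (log2 density 1.03, against 0.99 for H3). In watered leaves 167 bins passed and under PEG 161, all higher and all in the stretch, with 135 shared. The highest in watered leaves were chromosome 5, 17550001 to 17560000 with ATAUX2-11 (1.45 ± 0.17), 21790001 to 21800000 with the growth regulator GRF7 (1.43 ± 0.14), 21670001 to 21680000 with SDG29 (1.38 ± 0.15), 20130001 to 20140000 with TAS3b and MYB78 (1.34 ± 0.17) and 20000001 to 20010000 with MYB111 (1.33 ± 0.14). Under PEG they were 21540001 to 21550000 with the ion channel gene CNGC1 (1.85 ± 0.30), 21970001 to 21980000 with AT5G54145 (1.76 ± 0.26), 20410001 to 20420000 with FRO8 (1.70 ± 0.19), 19960001 to 19970000 with HRB1 and APRR4 (1.69 ± 0.19) and 18990001 to 19000000 with BOU (1.69 ± 0.25). No single gene passed: the smallest p-values in watered leaves were those of GRF7 (1.51 ± 0.18), the ribosomal protein gene RPL27 (1.48 ± 0.18), AT5G43720 (1.33 ± 0.18), AT5G53310 and AT5G42210 (1.64 ± 0.23), all at an adjusted p of 0.207. On the lower side, at 0.334 to 0.436, stood AT1G58561 (−1.20 ± 0.31), UGT75B2 (−0.78 ± 0.21), VHA-E2 (−0.60 ± 0.17), AT5G62340 (−0.88 ± 0.25) and AT2G20670 (−0.87 ± 0.25). Under PEG they were AT5G47300 (1.60 ± 0.19), RPL27 (1.59 ± 0.18), MIR166f (2.11 ± 0.25), AT5G42050 (1.68 ± 0.20) and AT5G43720. On the lower side stood AT4G08475 (−1.09 ± 0.18), GER2 (−1.19 ± 0.20), AT4G17180 (−1.09 ± 0.19), AT1G07860 (−1.06 ± 0.19) and AT1G01440 (−1.13 ± 0.20), at 0.132 to 0.135. By edgeR 0 genes passed in watered leaves (1833 at an unadjusted p under 0.05, DESeq2 548) and 0 under PEG (7316, DESeq2 2118). Leaving out any of the 4 libraries ended all bin calls in both treatments (watered Col0 replicates 1/2 and 3, PEG 1/2 and 3/4, mutant 1 and 2), as did fitting the compared groups alone, leaving out the stretch, or setting the change against H3. Library size scaling shifted changes by 0.23 and 0.27 and gave 0 and 448 bins. With coverage gaps as a covariate, more bins passed in each treatment than the stretch holds. Genes passed as well in this fit, so the calls were then not confined to the stretch (counts with the alternatives). A block for replicate number joined both mutant libraries to Col0 replicate 1/2, so the other Col0 library added nothing to its estimate.

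H3K4me3 reads in the mutant were higher on the stretch in watered leaves. Over both treatments their log2 density there was 1.095, against 0.99 for H3. Under PEG bins across the genome were called from 1 mutant library, where genotype and coverage gaps cannot be told apart. In watered leaves 246 bins passed, all higher and in the stretch, led by chromosome 5, 16190001 to 16200000 with AT5G40450 (2.53 ± 0.40), 17570001 to 17580000 with PnsB5 (2.12 ± 0.43), 17120001 to 17130000 with TRM30 (2.12 ± 0.45), 19500001 to 19510000 with MET18 (2.04 ± 0.53) and 21220001 to 21230000 with MYB19 (2.03 ± 0.42). The mutant side is 1 library, so these calls take their spread from the other groups. Of the genes 361 were called higher, 360 of them in the stretch, and 7 lower outside it. The microRNA gene MIR166e was higher by 3.14 ± 0.76 (4.76 CPM against 0.542 ± 0.296, SD, n = 2, adjusted p = 0.0109), the small RNA gene TAS3b by 3.01 ± 0.85, AT5G48515 by 2.94 ± 0.82, AT5G44830 by 2.84 ± 0.78 and AT5G48700 by 2.58 ± 0.73. Lower values had AT1G34042 (−1.81 ± 0.40), the defence gene AZI1 (−1.76 ± 0.46), AT3G25290 (−1.71 ± 0.47), AT2G41231 (−1.63 ± 0.45) and AT2G07850 (−1.46 ± 0.39). Without Col0 watered replicate 1/2 or 3 there were 0 bins, without replicate 1/2 0 genes, with coverage gaps as a covariate 0 of either, and by DESeq2 3 genes; library size scaling shifted changes by 0.23.

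Under PEG 3348 bins differed in H3K4me3 between the mutant and Col0, 1071 higher and 2277 lower, and 372 lay in the stretch. The mutant side is again 1 library, with its spread taken from the other groups. The lowest value was at chromosome 1, 10470001 to 10480000, which holds CAB1, CAB2 and CAB3, genes of the light-harvesting antenna of photosystem II (−2.97 ± 0.83). It was followed by chromosome 3, 16270001 to 16280000 with ADT4 (−2.71 ± 0.60), chromosome 1, 14150001 to 14160000 with NIA2, a nitrate reductase gene (−2.66 ± 0.59), chromosome 2, 12110001 to 12120000 with ARF10, an auxin response factor gene (−2.66 ± 0.61), and chromosome 1, 5440001 to 5450000 with LHCB6 (−2.65 ± 0.94). Among 10486 genes past the threshold, 4158 higher and 6328 lower, CAB3 had 18.7 CPM in the mutant against 210.0 ± 83.8 in Col0 (SD, n = 2; −3.49 ± 0.75, adjusted p = 1.98e-04), CAB2 −3.42 ± 0.82, AT1G64500 −3.38 ± 0.89, AT1G15825 −3.37 ± 0.81 and IBR10 −3.28 ± 0.82. The highest bins were poor in genes: chromosome 1, 14980001 to 14990000 (3.44 ± 0.81), 15010001 to 15020000 with AT1G40090 (3.13 ± 0.83) and 14930001 to 14940000 with AT1G40086 (3.12 ± 0.80), and chromosome 5, 21620001 to 21630000 (3.37 ± 0.85) and 17040001 to 17050000 (3.20 ± 0.81). Noncoding AT3G01805 and AT5G09035 had 59 and 41 reads in the mutant and 0 in Col0, at least 11.4-fold and 7.90-fold higher with the floor of 3 counts taken over the group; AT2G03931, AT5G03075 and AT5G07585 had 98, 93 and 126 reads against 1, 1 and 2, for which no fold is given. Both Col0 PEG libraries had coverage gaps and no mutant library had, so the batch and the genotype cannot be told apart here: with gaps as a covariate 0 bins and 1 gene passed, and relative to H3 0 bins. Library size scaling shifted all changes by 0.71, turning the split of bins to 4159 higher and 437 lower; without PEG replicate 3 there were 2200 bins and 3818 genes, and without PEG replicate 1/2 6756 genes.

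At the 2 targeted kinase loci no H3T3ph comparison passed. At AT5G18190 the log2 fold change of H3T3ph between mutant and Col0 was 0.07 ± 0.17 in watered leaves and 0.26 ± 0.16 under PEG, and at AT3G03940 (chromosome 3, 1013001 to 1020000) it was 0.14 ± 0.16 and 0.30 ± 0.15. Their relatives AT2G25760 and AT3G13670 stood at −0.02 and −0.33 in watered leaves and −0.04 and −0.09 under PEG. The H3K4me1 values, watered and PEG, were negative at AT5G18190 (−0.61 ± 0.20 and −0.87 ± 0.20), AT3G03940 (−0.54 ± 0.22 and −0.90 ± 0.23) and AT2G25760 (−0.36 ± 0.24 and −0.87 ± 0.24), and near 0 at AT3G13670 (0.01 and −0.07). None of these passed (adjusted p at least 0.166). Under PEG in Col0 the 4 loci had H3T3ph changes of −0.18, 0.00, 0.06 and −0.01 in the order AT5G18190, AT3G03940, AT2G25760 and AT3G13670. Chromatin at a locus does not measure its transcript, so the knockdown was not checked here.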

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

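The tests of coverage gaps, of the DNA copy, of the modification alone, of the bins with most reads, of the correlation between library sets, of the photosynthesis members under PEG, of other splits for H3 bins, and the count of splits that part all pairs, were chosen after the results were seen; those of enrichment strength and of other splits for H3 genes and the pericentromere list were written before their own result, but after the pattern they test.

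Chloroplast reads, which enter no comparison, took at least 0.537% of every H3T3ph library and at most 0.0425% of any H3 library. The double mutant H3 libraries, which have no bin or gene comparison of their own, carried a log2 density of at least 0.986 on the chromosome 5 stretch.

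The doubled density on the stretch of chromosome 5 was weighed against the set of libraries without coverage gaps, since all mutant libraries lack gaps. Col0 libraries without gaps reached at most 0.0983 there, which argues against that set as the cause. A change of the modifications on unchanged DNA is argued against by H3 itself, lowest 0.986 in mutant libraries. An additional copy of this DNA in the mutant line may account for it, with a mean log2 of 0.991 in H3, close to a doubling. Input DNA was not analysed here.

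The higher pericentromere to arm ratio of H3T3ph under PEG stays open between library set, repeats and treatment. Within libraries without gaps the difference was 0.0199, from 1 library against 1. Without the 1% of bins with most reads it was 0.114. Across 10 kb bins the changes in libraries with and without gaps had a correlation of −0.319, but of −0.0457 by ranks. With 1 or 2 libraries a side these values could come from noise as well as from a difference between sets.

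The higher H3K4me3 over photosynthesis genes under PEG may follow from stronger enrichment at every gene rich in this mark: the list's median stood at percentile 82.0 among 10000 random lists of the same watered level. With coverage gaps as a covariate the median was 0.449, which leaves the library set open. That 15 of 24 members were higher in both PEG than in both watered libraries restates the pattern, so the treatment stays open as well: both PEG libraries have gaps and only 1 watered library has.

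For H3 under PEG, 6 libraries make 10 splits, too few for a share under 0.05. The real split called 0 bins and 0 genes, so all 10 splits give as many by construction and this count says nothing. The split of watered 1/2, PEG 1/2 and PEG 3 against the others called 3243 bins and 10146 genes, which points to a structure of the samples. For the list of pericentromere genes 5 of 10 splits gave a p as small as the real 6.84e-04, the smallest other being 1.35e-09. Replicate numbers pair the H3 libraries, and the real split parts all 3 pairs, as 3 others do; the remaining 6 keep pairs together and so carry differences between pairs. Among the 4 that part all pairs, 3 gave a p as small.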

How the results depend on the processing

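The runs as replicates, the coverage gaps covariate, ratios relative to H3, the crossed block, the block and left-out libraries for gene lists, and leaving out the stretch were chosen after the data were seen. Of 454 alternatives to 35 results, 312 were counted as the same. For numbers of bins, genes or lists this means within a factor of 1.5, and for ratios an unchanged sign. The 10 ratios kept their sign in 91 alternatives and turned it in 10. For named genes, the same means an unchanged sign and side of the threshold. The 133 pairs of named gene and comparison had 1601 alternatives: 1265 the same, 233 weaker, 69 stronger and 32 changes of sign without a call. AT5G42965 (−0.33) and AT5G03075 (−1.62) reversed for gene body plus 1 kb. Values in the order H3T3ph, H3K4me1, H3K4me3 follow; the cause was not tested, except that leaving out the stretch removes the bins it holds.
With 100 kb bins H3K4me3 under PEG gave 0 bins, and mutant against Col0 61, 58 and 56 watered and 60, 64 and 99 under PEG. DESeq2 gave 52 bins for H3K4me3 under PEG and 480 and 1846 for H3K4me1 in the mutant (watered, PEG), and genes 1592 for H3K4me3 under PEG, 1171, 548 and 3 in watered and 1150 and 2118 in PEG mutants. An estimated correlation left 0 lists. With coverage gaps as a covariate H3K4me3 under PEG gave 0 bins and 2 genes, watered mutants 710, 4632 and 0 bins and 1808, 9298 and 0 genes, PEG mutants 4398 and 0 bins for H3K4me1 and H3K4me3 and 1393, 10365 and 1 genes. Each run as a replicate gave 2392 bins for H3K4me3 under PEG, 407 and 1752 for mutant H3K4me1, 4184 and 8726 for mutant H3K4me3, and an H3K4me1 ratio of 0.22. Gene body plus 1 kb gave 979 and 1134 genes for mutant H3T3ph and 607 for watered mutant H3K4me3. Library size gave 1 bin and 10 genes for H3K4me3 under PEG, 0 and 448 bins for mutant H3K4me1, and 0, 671, 3879 and 21182 genes for watered H3T3ph, watered H3K4me3, PEG H3K4me1 and PEG H3K4me3 in the mutant. Medians gave ratios under PEG of 0.0381 (H3K4me1) and −0.0288 (H3K4me3), and leaving out the top 1% of bins −0.0521 (H3K4me3). Single left-out libraries turned the sign to 0.42 (H3K4me1 without PEG 1/2), 0.0633 (H3 without watered 4) and −0.0257 (mutant watered H3T3ph without Col0 3/4). Only the groups compared gave 0 and 0 bins for mutant H3K4me1, 371 and 309 for H3K4me3 and 0 genes for H3T3ph in both. Relative to H3 all 6 mutant bin comparisons and H3K4me3 under PEG gave 0. A block for replicate number gave bins 21 (H3T3ph under PEG), 10 (H3), 0 (H3K4me3), 210 (H3T3ph under PEG in the mutant), 2062 and 1010 (mutant H3T3ph), 5028 and 7880 (mutant H3K4me1). It gave 10 lists, 3 of them H3T3ph lists higher in PEG (adjusted p 1.72e-04 for osmotic and ABA response, 0.00166 for photosynthesis, 0.0274 for pericentromere genes). The block was not fitted with an estimated correlation, which without the block gave these 3 lists an adjusted p of 0.881. It gave genes 334, 18, 5964, 3061, 14072 and 22877 (H3T3ph and H3K4me3 under PEG, mutant H3T3ph, mutant H3K4me1). For Col0 H3T3ph the block left PEG 4/5 in a block of its own, so that library added nothing to the estimate. Between genotypes it joined both mutant libraries to Col0 replicate 1/2, so those counts rest on that Col0 library alone. A crossed block gave 667 bins for H3K4me3 under PEG. Scaling on the arms gave 85 bins and 25 genes for H3K4me3 under PEG, 0 and 388 bins for watered mutant H3K4me1 and H3K4me3, and 0, 605, 3124 and 19060 genes in the order given for library size. Without the stretch 0 bins passed for mutant H3T3ph and H3K4me1 in both treatments and for watered H3K4me3.
Without H3K4me3 PEG 3, 265 bins passed under PEG, without mutant H3T3ph 1 273 watered, and without Col0 H3T3ph PEG 3 387. Leaving out 1 library at a time gave bins of 0 to 624 (H3K4me3 under PEG), 220 to 490 and 205 to 612 (mutant H3T3ph), 0 to 0 (mutant H3K4me1, both), 0 to 0 and 2200 to 4368 (mutant H3K4me3) and 0 to 26 (H3K4me3 interaction); genes of 1 to 1162, 0 to 94, 0 to 298, 0 to 1023 and 3818 to 6756 (H3K4me3 under PEG, then mutant watered H3T3ph, watered H3K4me3, PEG H3T3ph and PEG H3K4me3). It gave lists of 1 to 8, with 8 without H3T3ph PEG 4/5, 6 without H3 watered 1/2 or PEG 4, 5 without H3K4me1 watered 3, H3T3ph watered 1/2 or 3/4, H3 PEG 3 or H3K4me3 PEG 1/2, and 1 without H3 watered 4. Ratios under PEG moved between 0.09 and 0.21 (H3T3ph), −0.18 and 0.20 (H3), −0.91 and 0.78 (H3K4me1), and −0.42 and 0.58 (H3K4me3). They moved for mutant against Col0 between −0.03 and 0.05 and between −0.24 and −0.12, in the mutant between −0.05 and −0.04, and against H3 between −0.35 and −0.11, −2.00 and −0.31, and −1.66 and −1.41.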

Other observations

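The values in this part carry no test and were chosen after the data were seen.

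Levels relative to H3 in watered Col0 are given here by gene group. Photosynthesis genes had a median log2 of 1.22 ± 0.55 for H3K4me3 (SD, n = 2) and −0.81 ± 0.29 for H3T3ph, while developmental and seed genes had −0.79 ± 0.21 for H3K4me3 and 0.30 ± 0.45 for H3T3ph. Osmotic and ABA response genes stood at −0.01 for H3K4me3 and −0.26 ± 0.05 for H3T3ph. Pericentromere genes had −1.30 ± 0.13 for H3K4me3, −1.19 ± 0.87 for H3K4me1 and −0.02 ± 0.02 for H3T3ph. Under PEG, photosynthesis genes stood at 2.04 ± 0.39 for H3K4me3 and −0.56 ± 0.31 for H3T3ph.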
